A study of Drosophila melanogaster with 12 samples.

How the data were processed

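Total RNA was taken from the eye discs of wandering larvae in 12 samples, 3 in each of 4 groups, with 30 pairs of discs per preparation. Libraries were made with a stranded total RNA kit that removes ribosomal RNA and were sequenced on a HiSeq-2500 as 50 bp read pairs, with 12 samples per lane and each sample spread over 2 lanes, per the labels' protocols. The labels place each sample in its group and do not say whether the 3 samples of a group came from separate crosses, so the p-values measure only the spread between these samples, which may be technical.

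The submitters' processing notes name TopHat, Bowtie, Cufflinks, Cuffdiff 2.1.1 and the genome build dm6. Versions of the first 3 tools, the gene annotation, filters and whether reads were counted by strand are not given in the sources used here. The deposited data are 6 tables, one for each pair of groups, with 15903 or 15904 gene rows each. The authors deposited 1 FPKM value per gene and group, pooled over the samples of that group by Cuffdiff, so no value per sample, SD or n stands behind a printed level. Each table also holds the authors' log2 fold change of the second group over the first and a test statistic, a score with no fixed range. The authors' p-value and q-value complete each row, per the file headers. The deposited q matched a Benjamini-Hochberg adjustment over all 65927 tests with status OK in the 6 tables, with a largest difference of 1.56e-05. The smallest deposited p-value was 5e-05, which corresponds to the smallest q-value, 0.00789, and 418 tests held that p-value. An unnamed flag column in the authors' tables was equal to a p-value at or under 0.05 in every row, with 0 exceptions. One input label in the authors' tables lists a sample of the hsrω RNAi group as 2 inputs, so that this group entered Cuffdiff with 4 inputs for 3 samples. Because only FPKM values were used, the read depth of each sample is unknown, and no interval or detection floor that needs counts was computed.

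A gene was called when its status was OK and its deposited q was at or under 0.05, the authors' test being used as deposited. This test, the comparisons, the gene lists, the alternatives and the rule for named genes were set before the data were examined, apart from 4 alternatives and 2 gene lists that were added after the data were seen. The 4 main comparisons were control with Ras, Ras with each of the groups labelled hsrω RNAi and EP3037, and these last groups with each other; the 2 combined comparisons set them against the control. Genes at 0 FPKM in a group are described as listed at 0, with no fold change. Rows that name several genes at one locus, 637 in all, are printed with every name they hold. Genes were matched to Ensembl release 115 (BDGP 6) by symbol, synonym or exact locus: 15174 rows matched and 14980 of these overlapped the annotated gene. Chromosomes, starts and ends are those of the authors' tables on dm6, and strand, biotype and the length of the longest annotated transcript are from the annotation. Reads of overlapping genes, antisense genes and near-identical copies cannot be assigned with certainty from these tables. Most such genes are marked as uncertain or as overlapping other rows where they are first named in the results, and not at each later mention.

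The named genes of each main comparison were Hsromega, Ras85D and sev; the 8 largest rises and 8 largest falls among called single-gene rows with at least 1 FPKM in both groups and a genomic span of at least 200 nt; up to 4 members of each enriched list and of 6 lists always described; and up to 3 called genes listed at 0 in 1 group. The combined comparisons used 4 rises and 4 falls. Genes named outside this rule are said to be chosen after their values were seen.

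Gene lists numbered 36. They were Ras MAPK components, Ras targets and feedback, photoreceptor fate, cone and pigment cells, neuronal differentiation, retinal determination, the Notch pathway, Hedgehog, Dpp, Wg and JAK-STAT signalling, the Hippo pathway, the cell cycle, apoptosis, JNK and wound response, heat shock, hnRNP and omega speckle proteins, splicing factors, cytosolic ribosomal proteins, ribosome biogenesis, snoRNA, snRNA, tRNA, microRNA, histone genes, ecdysone response, antimicrobial peptides and immunity, glycolysis, glutathione transferases with cytochromes P450, cuticle proteins, chromatin regulators and sex-related genes. Markers of fat body, salivary gland, haemocytes, muscle, glia, antennal disc with peripodial cells, and brain neurons completed them. The 2 lists added later were ring gland steroid enzymes and midgut digestive enzymes. Each list was tested for an excess of higher and, separately, of lower calls with a two-sided Fisher's exact test against all genes tested in that comparison, with Benjamini-Hochberg adjustment over the lists and both directions. The test treats genes as independent, and correlation between genes cannot be estimated from pooled values. Its p-values may therefore be too small for genes that move together. The median log2 fold change of each list was placed among 10000 random lists of the same size matched on mean FPKM, and its p-values were also adjusted over the list alone.

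Overlaps of calls between comparisons that share the Ras libraries were set beside the overlap of independent lists and beside 1000 simulations of unchanged groups against shared Ras libraries. The noise was normally distributed, and its size for each gene was that which turns the log2 fold change into the deposited p-value. At the smallest deposited p-value, 5e-05, the median over the gene's other comparisons was used where it was smaller. A trend of log2 fold change on transcript length was fitted with lowess (span 0.3) over genes with at least 1 FPKM in both groups. The alternatives set in advance were a q of 0.01, a 2-fold minimum, adjustment within each comparison, a minimum of 1 FPKM, a minimum span of 200 nt, pseudocounts of 0.1 and 1, centring on the median and the background of the list test. Those added later were the unadjusted p-value, the removal of other tissues' markers, the subtraction of the length trend and a test rescaled to 3 inputs for the hsrω RNAi group. Leaving out single samples, a replicate block and other splits of the samples need values per sample and were left out. The scripts were tested on simulated data for the comparison of the hsrω RNAi and EP3037 groups: among 8582 genes, 49% of planted 2-fold and 86% of planted 4-fold changes were recovered, with 1 of 8382 unplanted genes called. With a planted length trend the script called 29 unplanted genes, and 6 after the trend was subtracted. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.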

Results

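RNA from the eye discs of wandering larvae, the tissue that forms the compound eye, was measured in 4 groups of 3 Drosophila melanogaster samples. All groups carried sev-GAL4, a driver active in sevenless-expressing cells of the disc, together with UAS-GFP. The control had no activated Ras, the Ras group expressed RasV12, a constitutively active Ras, and the remaining groups expressed RasV12 with an RNAi construct against the long noncoding RNA hsrω or with EP3037, an insertion whose label says that hsrω is raised. The labels list the allele dco2 in the control and Ras groups and not in the RNAi and EP3037 groups, so it differs along with hsrω. Levels are the authors' FPKM, 1 pooled value per gene and group, so no SD, n or count of samples in one direction stands beside them. Each group had between 9213 and 9428 of 15904 gene rows at 1 FPKM or more. Depth is unknown, since FPKM values carry no read totals. A gene named as risen or fallen below passed a q of 0.05 in Cuffdiff. Where its fold for that comparison is printed in the report with no q, the q was the smallest in the authors' deposited tables, 0.00789. Genes named for a comparison with neither its fold nor its q had a q from that value up to 0.05.

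The manipulated genes were read first. Hsromega, the gene of hsrω (chromosome 3R, 21296127 to 21317836, plus strand, noncoding), was at 543 FPKM in the control, 389 in the Ras group, 398 in the group labelled hsrω RNAi and 606 in the group labelled EP3037. Its log2 change from Ras was 0.04 in the RNAi group (p = 0.966) and 0.64 in the EP3037 group (p = 0.486) in the authors' deposited tables, and neither was called. The pooled level in whole discs was therefore not lower in the RNAi group than in the Ras group. The test of this gene was imprecise, since even a log2 change of 0.64 was far from being called. A fall of hsrω in the RNAi group is thus neither shown nor excluded, and these groups are named by their labels throughout. Ras85D, the Ras gene itself (chromosome 3R, 9510561 to 9513067, minus strand, protein-coding), was at 74.4 FPKM in the control, 121 in Ras, 151 in the RNAi group and 142 in the EP3037 group; its reads can come from the transgene as well as from the endogenous gene. Against the control it rose 2.03-fold in the RNAi group and 1.91-fold in the EP3037 group, while the 1.62-fold difference in the Ras group missed the threshold (q = 0.0509 in the authors' deposited table). The receptor gene sev (chromosome X, 11071441 to 11086299, minus strand, overlapping 1 other row) was at 22.6, 28.4, 36.8 and 29 FPKM in the same order and rose 1.63-fold from control to the RNAi group alone among the 6 comparisons (q = 0.0359 in the authors' deposited table).

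**Figure D1:**
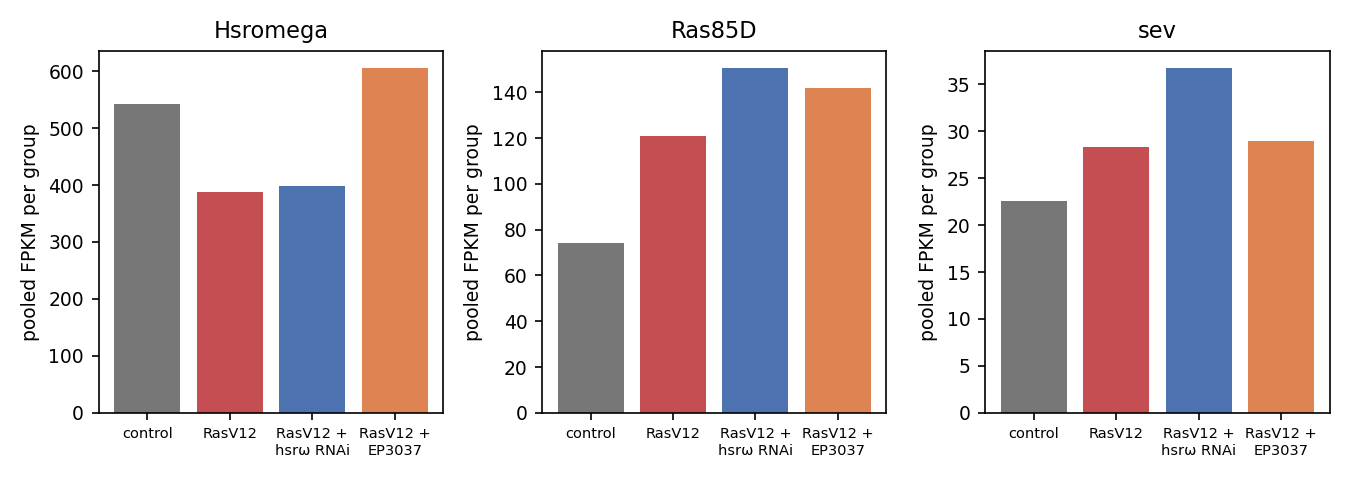
Bars give the authors' pooled FPKM (vertical axis, from 0) of Hsromega, Ras85D and sev in each of the 4 groups, with no error bars because no values per sample were used. Hsromega stood at 389 in the Ras group and 398 in the group labelled hsrω RNAi, and Ras85D at 74.4 in the control against 121 to 151 in the groups with RasV12.

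Activated Ras under sev-GAL4 was compared with the control to ask what it changes in the eye disc. Of the tested genes, 3 of 31 ecdysone response genes, 2 of 70 cuticle genes and 2 of 28 neuronal genes rose. Lower were 4 of 12 fat body and 2 of 16 haemocyte markers. No sort or gate separated disc cells from other tissue, so these falls cannot be assigned to RasV12 alone. Lcp4, a larval cuticle protein, rose 9.15-fold, from 8.51 to 77.9 FPKM. The nuclear receptor Hr4 rose 3.15-fold (5.40 to 17.0 FPKM, overlapping 1 other row), and Blimp-1, an ecdysone-induced repressor of ftz-f1, rose 2.39-fold to 31 FPKM. ImpL3, lactate dehydrogenase, fell from 17.4 to 6.92 FPKM. Of 10996 tested genes, 46 were higher and 39 lower in the Ras group, and 33 higher and 44 lower once the trend of fold change with transcript length was subtracted.

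Among 31 tested ecdysone response genes 3 were higher and 1 was lower, the higher ones being Hr4, Blimp-1 and the row CG12912,Hr46, which holds another ecdysone-regulated receptor and was 2.83-fold higher; the lower one was ImpL3. Fisher's exact test gave an adjusted p of 0.00993 for the higher calls, and the list's median log2 change of 0.29 lay at percentile 99.99 of matched random lists. Adjusted over the list alone, 4 were higher and 1 lower. Subtracting the length trend, an alternative added after the data were seen, ended this enrichment, with an adjusted p of 0.0673. Neuronal differentiation had 2 higher of 28 (adjusted p = 0.0705, 4 adjusted over the list alone), the presynaptic scaffold gene brp (1.69-fold, q = 0.0284 in the authors' deposited table) and the row Gr2a,futsch, which holds a neuronal microtubule protein (1.95-fold, q = 0.0192 in the authors' deposited table). Other large rises were in roX2, a noncoding RNA of the male dosage compensation complex (5.65-fold, to 517 FPKM), CG18547 (3.40-fold), CG11966 (2.79-fold, q = 0.0140 in the authors' deposited table), tnc, which encodes an extracellular matrix protein (2.67-fold), phr, a DNA photolyase (2.55-fold, overlapping 1 row), and bnb, a gene expressed in glia (2.47-fold, overlapping 3 rows).

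Markers of fat body were lower in 4 of 12 cases, with 0 higher, and a median log2 change of -0.99 (adjusted p = 4.59e-06 by Fisher's exact test, 4 adjusted over the list alone). The larval serum proteins Lsp1gamma, Lsp1alpha and Lsp2 fell 4.52-fold, 3.71-fold and 3.29-fold and the receptor Fbp1 fell 2.67-fold, from between 6.06 and 14.3 FPKM in the control; the Lsp1 genes are close copies, so their separate values are uncertain. Haemocyte markers were lower in 2 of 16 cases, with a median of -0.39. These were the row CR45660,Pxn, which holds peroxidasin (2.09-fold), and Hml, hemolectin (1.78-fold, q = 0.0192 in the authors' deposited table). Their adjusted p of 0.0333 became 0.0634 after the length trend was subtracted and 0.399 at a q of 0.01, and 4 were lower adjusted over the list alone. Among 23 heat shock genes 2 were lower, Hsp70Bc (6.52-fold, from 3.70 FPKM) and the co-chaperone DnaJ-1 (1.82-fold, from 101 FPKM, q = 0.0192 in the authors' deposited table), with an adjusted p of 0.0505, or 0.0450 against a background of genes at 1 FPKM or more, and the same 2 adjusted over the list alone. Hsp70Bc shares reads with near-identical copies and is uncertain; Hsp70Bb, one of them, was at 12.2 FPKM in the control and 19.4 in the Ras group without being called. The other large falls were the noncoding CR40469 (80.9-fold, from 2249 to 27.8 FPKM), Sirup, a mitochondrial assembly factor (4.93-fold, from 90.1 to 18.3 FPKM, overlapping 1 row), the noncoding CR45108 (4.79-fold, overlapping 1 row) and the odorant-binding proteins Obp99b (3.72-fold, q = 0.0399 in the authors' deposited table) and Obp56d (3.43-fold, q = 0.0359 in the authors' deposited table). CG6149 was listed at 0 in the control and at 1.89 FPKM in the Ras group, and CG33766 and CG33769, at 1.77 and 1.68 FPKM in the control, were listed at 0 in the Ras group.

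The lists closest to the Ras pathway held 0 Cuffdiff calls from control to Ras. Of 35 Ras MAPK components 2 had an unadjusted p at or under 0.05, both higher, and the same number passed when adjusted over the list alone; these were Ras85D, whose reads can come from the transgene, and MESR4 at 13.6 and 21.0 FPKM. The nuclear Ras pathway gene spen was at 68.5 and 94.3 FPKM (p = 0.142 in the authors' deposited table). Of 27 Ras targets and feedback genes 5 had an unadjusted p at or under 0.05, all higher, including mirr at 7.95 and 12.9 FPKM and rno at 14.5 and 22.4, with 0 adjusted over the list alone. Among 30 photoreceptor fate genes the count was 2, both higher, with salm at 11.6 and 16.6 FPKM. The 22 apoptosis genes gave 0 at that level, with the Drosophila TNF gene egr at 8.31 and 11.2 FPKM (overlapping 1 row). The 32 hnRNP and omega speckle genes gave 1, the smooth gene sm, at 10.7 and 21.9 FPKM and overlapping 5 rows, which also passed when adjusted over the list alone.

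Ras and the group labelled hsrω RNAi were compared to ask what this construct changes when Ras is active. The direction is that of the label. The pooled level of Hsromega was too imprecise to show whether hsrω was lowered. Of 16 haemocyte markers 8 rose, 6 of 73 cuticle genes and 3 steroid-synthesis genes fell, and photoreceptor and Ras pathway lists held no call. The medians of the photoreceptor and Ras pathway lists lay above 0, as did those of other lists such as cell cycle and hnRNP genes. Hml rose 2.63-fold, from 4.10 to 10.8 FPKM, and PPO2, a prophenoloxidase of crystal cells, rose 2.47-fold, to 64.7 FPKM. Lcp4 fell 27.5-fold, from 77.9 to 2.83 FPKM, and spok, an enzyme of ecdysone synthesis in the ring gland, fell 3.6-fold, from 53.9 to 15.0 FPKM. Of 10897 tested genes, 19 were higher and 62 lower.

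Haemocyte markers were higher in 8 of 16 cases and lower in 0, with a median log2 change of 1.12 and 9 higher adjusted over the list alone (adjusted p = 1.37e-17 by Fisher's exact test). Markers of a tissue can move together while the test treats them as independent. This p-value and those of the other tissue lists may therefore be too small. Beside Hml and PPO2 these were the row CR45660,Pxn (2.56-fold), the basement membrane glycoprotein gene Glt (2.41-fold, overlapping 1 row), PPO1 (overlapping other rows), the collagen genes Cg25C and vkg, and the phagocytic receptor eater. The last 4 rose by 1.10, 1.13, 1.15 and 1.2 on the log2 scale, with q = 0.0284 for eater in the authors' deposited table. Without the markers of other tissues, an alternative added after the data were seen, 11 genes were higher in place of 19. Ecdysone response genes were higher in 2 of 29 cases, the glycolytic enzyme gene ImpL3 (5.18-fold, to 35.8 FPKM) and Sb, a protease of disc eversion (2.27-fold), with an adjusted p of 0.0265 and 3 higher and 1 lower adjusted over the list alone. The remaining large rises were CG10126 (10.5-fold, from 1.15 to 12.1 FPKM), Sirup (4.47-fold, to 81.6 FPKM, overlapping 1 row), NtR, which encodes a predicted ligand-gated ion channel subunit (2.89-fold, overlapping 1 row, q = 0.0399 in the authors' deposited table), and CG45087 (2.42-fold).

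**Figure D2:**
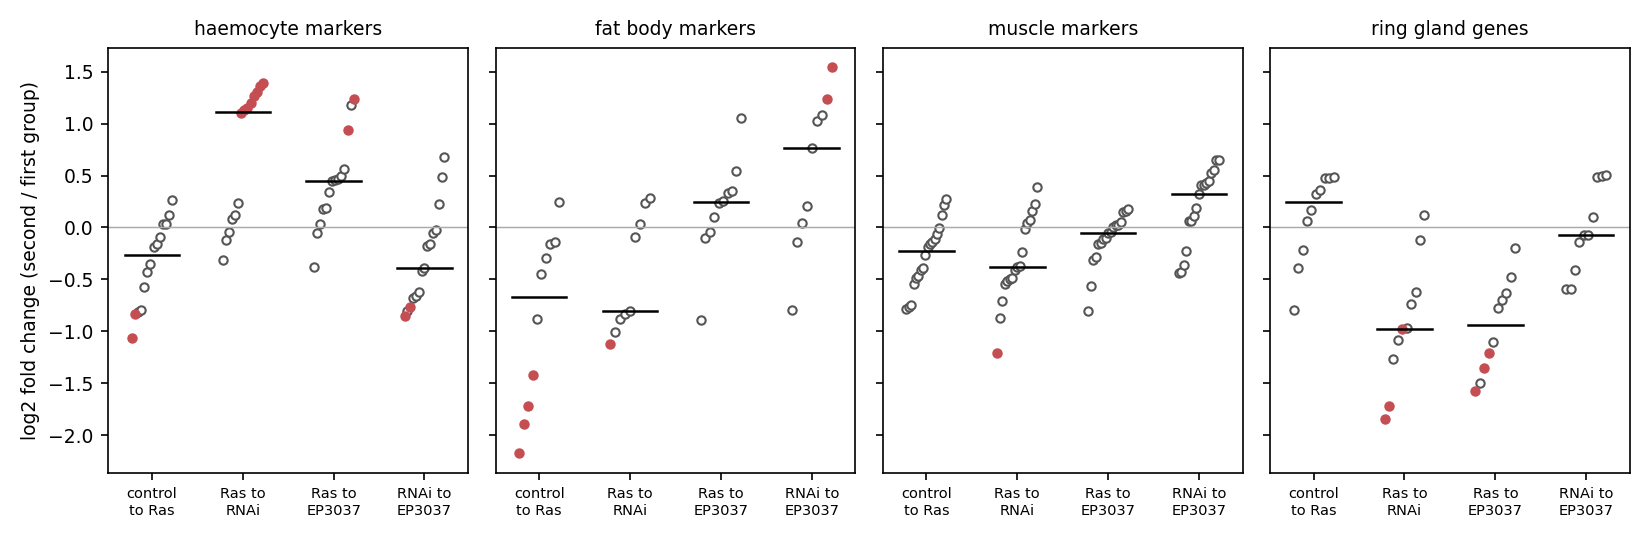
Points give the authors' log2 fold change (vertical axis) of each haemocyte, fat body and muscle marker and each ring gland gene at 1 FPKM or more in both groups, in the 4 main comparisons. Filled points are called at q of 0.05 and lines are medians; 8 haemocyte markers were called higher from the Ras group to the group labelled hsrω RNAi, and 3 ring gland genes were called lower in each of the comparisons from Ras.

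Cuticle proteins were lower in 6 of 73 cases (adjusted p = 0.000117 by Fisher's exact test, 7 adjusted over the list alone), while the list's median log2 change, over the 70 with a finite value, was -0.01, at percentile 53.93 of matched random lists. Beside Lcp4 these were Lcp1 (11.3-fold, from 13.6 to 1.2 FPKM), Cpr51A, which fell by 1.00 on the log2 scale (q = 0.0140 in the authors' deposited table), and TwdlN, TwdlO and Cpr47Eb, at 2.13, 1.08 and 0.674 FPKM in the Ras group and listed at 0 in the RNAi group. CG30457 was likewise at 1.11 FPKM in the Ras group and listed at 0. Other large falls were in nvd, which acts in the first step of ecdysone synthesis (3.28-fold), the histone gene copy His2B:CG33868 (3.31-fold, one of many near-identical copies and uncertain), CG34247 (3.09-fold, q = 0.0399 in the authors' deposited table), roX2 (2.96-fold, to 175 FPKM) and the noncoding CR42861 (2.79-fold, q = 0.0469 in the authors' deposited table). Lower calls had a median transcript length of 792 nt against 1829.5 nt for all tested genes, and 26 were higher and 27 lower in place of 19 and 62 after the length trend was subtracted. Fat body markers had a median log2 change of -0.83 with 1 of 11 lower, Lsp1beta (2.18-fold, q = 0.0399 in the authors' deposited table), and 5 lower adjusted over the list alone. Salivary gland markers had a median of -1.30 over 9 tested with 0 Cuffdiff calls and 3 lower at an unadjusted p at or under 0.05; the 4 of them at 1 FPKM or more in both groups had a median of -0.31, and -0.07 after the length trend was subtracted.

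No member of the other lists of direct interest was called by Cuffdiff from Ras to the group labelled hsrω RNAi, and none passed adjusted over the list alone. At an unadjusted p at or under 0.05, 5 of 30 photoreceptor fate genes were higher, among them the fate gene phyl at 11 and 17.3 FPKM and ro at 6.37 and 11.3 FPKM, the latter overlapping 1 row. The same held for 4 of 27 Ras targets, among them the feedback inhibitor sty at 49.8 and 75.7 FPKM, overlapping 1 row. None of 35 Ras MAPK components and none of 32 hnRNP genes had such a p, and 1 of 22 apoptosis genes did, Traf4 at 29.2 and 42.8 FPKM (overlapping 1 row). Of 23 heat shock genes 3 were higher and 2 lower at that level, and Hsp26, a small heat shock protein, was at 246 and 361 FPKM. The medians of the photoreceptor fate and Ras target lists, 0.22 and 0.18, lay at percentile 100 of matched random lists, which were not matched on length. For the 29 photoreceptor genes at 1 FPKM or more the median was 0.25, and 0.20 after the length trend was subtracted. Cell cycle genes, with a median of 0.12, and glycolysis genes, with 0.20, also lay at percentile 100. Neuronal, Ras MAPK, hnRNP and chromatin lists lay at 99.98, 99.89, 99.85 and 99.78, so a high percentile was not particular to photoreceptor or Ras target genes. Notch and apoptosis lists lay at 63.5 and 37.4, and snoRNA, snRNA and microRNA lists at 0.

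The EP3037 group was set against Ras with the corresponding question, what a label of raised hsrω goes with when Ras is active. Several genes that stood high in the Ras group fell, among them Lcp4 (4.76-fold, to 16.4 FPKM), bnb (3.09-fold, from 109 to 35.1 FPKM, overlapping 3 rows) and tnc (3.05-fold, from 42.9 to 14.1 FPKM). Thor, the translational repressor 4E-BP, fell 4.33-fold, from 17.4 to 4.02 FPKM. Enzymes of ecdysone synthesis fell as well, phm 2.97-fold (to 12.0 FPKM) and spok 2.56-fold. CG30345 rose 6.53-fold, from 1.32 to 8.60 FPKM. Of 11062 tested genes, 20 were higher and 67 lower. Lower calls had a median transcript length of 3876.5 nt against 1811 nt for all tested genes, and 30 were higher and 39 lower after the length trend was subtracted.

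Further falls were in AGO3, which encodes an Argonaute protein of the piRNA pathway (2.63-fold, q = 0.0192 in the authors' deposited table), and the peptidase gene SP1029 (2.60-fold). Further rises were in the unannotated row CR40976 (2.94-fold), CG12643 (2.76-fold), the noncoding CR43148 (2.75-fold), regucalcin (2.19-fold, overlapping 1 row, q = 0.0359 in the authors' deposited table), CG31817 (2.12-fold) and dnr1, which encodes an inhibitor of the caspase Dredd (1.78-fold, q = 0.0140 in the authors' deposited table). Lcp65Ag3, CG18294 and TwdlN, at 7.57, 5.77 and 2.13 FPKM in the Ras group, were listed at 0 in the EP3037 group. Haemocyte markers were higher in 2 of 16 cases, with a median log2 change of 0.45 (adjusted p = 0.0257 by Fisher's exact test, 3 adjusted over the list alone). They were Hml (2.36-fold) and the row CR45660,Pxn (1.91-fold, q = 0.0469 in the authors' deposited table), and the adjusted p became 0.0583 after the length trend was subtracted and 0.453 at a q of 0.01.

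Of 30 ecdysone response genes 2 were lower from Ras to EP3037, Blimp-1, which fell by 1.21 on the log2 scale to 13.4 FPKM, and the row CG12912,Hr46, which fell by 1.30 (q = 0.0284 in the authors' deposited table). The excess was not called, 3 were lower adjusted over the list alone, and the list's median of -0.28 lay at percentile 0.04; for the 28 at 1 FPKM or more it was -0.14 after the length trend was subtracted. One of 35 Ras MAPK components fell, MESR4 (1.74-fold, q = 0.0140 in the authors' deposited table), named as a misexpression suppressor of Ras, and 1 of 27 Ras targets, rno, a nuclear protein of Egfr signalling in the eye (1.88-fold, q = 0.0140 in the authors' deposited table). Adjusted over each list alone these lists had 1 and 4 lower. Photoreceptor fate genes had 0 Cuffdiff calls, and 4 of 30 were lower at an unadjusted p at or under 0.05, with chp, a photoreceptor adhesion protein, at 16.4 and 11 FPKM. The 22 apoptosis genes had 0 at either level. Of 32 hnRNP genes 2 were lower at the unadjusted level and 0 were called, with glo at 59.9 and 43.0 FPKM. The 22 heat shock genes also had 0 calls and, at the unadjusted level, 1 higher, Hsp70Bb, and 3 lower, with 1 higher and 1 lower adjusted over the list alone.

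The groups labelled hsrω RNAi and EP3037 were compared with each other, which tests their difference itself. In the EP3037 group 4 proteases rose among 20 tested digestive enzymes of the midgut. Lower calls lay on long transcripts and held 4 of 30 chromatin regulators, 4 of 27 Ras targets and 2 of 35 Ras MAPK components. Enrichment of the chromatin and Ras target lists was lost once the length trend was subtracted. Jon65Aiii rose 24.4-fold, from 1.46 to 35.6 FPKM, and yip7, Jon65Aiv and Jon25Bi, of the same kind of protease, rose 19.5-fold, 12.1-fold and 10.9-fold. ImpL3 fell 3.91-fold, from 35.8 to 9.16 FPKM, and bnb 4.11-fold (overlapping 3 rows). Of 10981 tested genes, 24 were higher and 167 lower in the EP3037 group. Lower calls had a median transcript length of 5804 nt against 1816 nt for all tested genes, and 35 were higher and 72 lower after the length trend was subtracted.

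Among the other named genes, Sirup (3.31-fold, overlapping 1 row), Thor (3.23-fold, q = 0.0140 in the authors' deposited table), the transmembrane protease gene Np (3.04-fold), tnc (2.91-fold), CG10126 (2.88-fold) and CG14814 (2.67-fold) fell. Lcp4 (5.79-fold, q = 0.0192 in the authors' deposited table), CG12643 (4.73-fold), CG30345 (3.74-fold) and CR40976 (3.62-fold) rose. CG18294, at 5.03 FPKM in the RNAi group, was listed at 0 in the EP3037 group, and CG32198 and CG3397, listed at 0 in the RNAi group, were at 0.825 and 0.417 FPKM (q = 0.0240 for CG32198 in the authors' deposited table). Fat body markers were higher in 3 of 12 cases, Lsp1alpha (4.38-fold), Lsp1gamma (2.92-fold, q = 0.0192 in the authors' deposited table) and Lsp2 (2.35-fold, q = 0.0438 in the authors' deposited table). Their median log2 change was 1.06, with an adjusted p of 0.000139 by Fisher's exact test and 4 higher adjusted over the list alone; counting only calls at a q of 0.01, the adjusted p was 0.307.

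Of 27 Ras targets and feedback genes 4 were lower in the EP3037 group, rno (2.04-fold), the homeodomain gene mirr (1.81-fold), the T-box gene mid (1.74-fold, q = 0.0140 in the authors' deposited table) and cic, a repressor that Ras signalling inactivates (1.83-fold, q = 0.0359). Fisher's exact test gave an adjusted p of 0.0241, with 7 lower adjusted over the list alone, and 0.156 after the length trend was subtracted. Chromatin regulators were lower in 4 of 30 cases, with 7 adjusted over the list alone: the Polycomb group genes Psc (1.86-fold) and ph-d (1.69-fold), and brm (1.82-fold, overlapping 2 rows) and osa (1.94-fold, q = 0.0469 in the authors' deposited table) of the SWI/SNF complex. Their adjusted p of 0.0242 became 1.00 after the length trend was subtracted. Both lists also lost the enrichment at a q of 0.01, with adjusted p of 0.307 and 0.117.

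Ras MAPK components fell in 2 of 35 cases, MESR4 (1.80-fold) and the row CG12020,Cdc37, which holds a kinase co-chaperone (1.70-fold, q = 0.0469 in the authors' deposited table), with 4 adjusted over the list alone. Of 30 photoreceptor fate genes 2 fell, the zinc finger gene salm (1.77-fold) and the row CG17724,Kdm4B,seq (1.77-fold, q = 0.0438 in the authors' deposited table), with 7 adjusted over the list alone. Among 23 heat shock genes stv fell 1.82-fold (q = 0.0140 in the authors' deposited table), the only one also when adjusted over the list alone. Neither hnRNP nor apoptosis genes were called by Cuffdiff: at an unadjusted p at or under 0.05, 8 of 32 hnRNP genes were lower, among them glo at 64.3 and 43.0 FPKM and Hrb87F at 125 and 93.6, and 1 of 22 apoptosis genes was higher and 1 lower. Neither list had a member that passed adjusted over the list alone. With no enrichment, haemocyte markers were lower in 2 of 16 cases (PPO2 and PPO1), ecdysone response genes in 2 of 29 (ImpL3 and Eip75B) and neuronal genes in 3 of 28 (the row Gr2a,futsch, brp and cpo). Adjusted over each list alone, 6 haemocyte markers were lower and 1 higher, and 6 ecdysone and 3 neuronal genes were lower. The ecdysone median of -0.40 lay at percentile 0 of matched random lists. For the 28 ecdysone genes at 1 FPKM or more it was -0.20 after the length trend was subtracted. The median of the 26 neuronal genes at 1 FPKM or more was -0.20, and 0.11 after the length trend was subtracted.

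**Figure D3:**
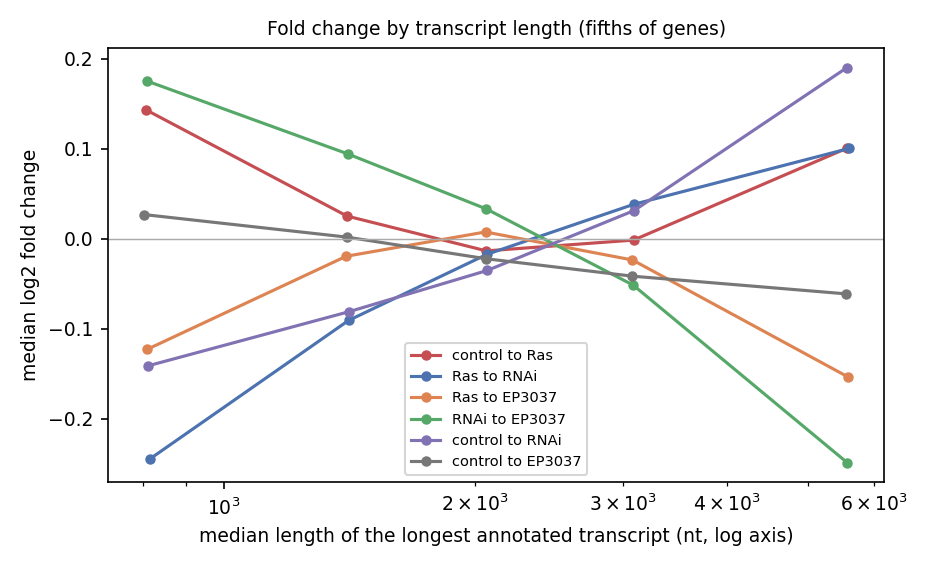
Lines give the median log2 fold change (vertical axis) of genes at 1 FPKM or more in both groups, split into 5 groups of equal size by the length of the longest annotated transcript (horizontal log axis, nt), for each of the 6 comparisons. From the group labelled hsrω RNAi to the EP3037 group the median went from 0.18 in the shortest transcripts to -0.25 in the longest, and from Ras to the RNAi group from -0.24 to 0.10.

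The fold changes followed transcript length across genes in the comparisons with the RNAi group. The Spearman correlation across genes, which are not independent replicates, was 0.44 from Ras to the RNAi group, -0.44 from the RNAi to the EP3037 group and 0.37 from control to the RNAi group. It was -0.02 from control to Ras, -0.06 from Ras to EP3037 and -0.12 from control to EP3037, 6 such values in all, given with no p-value. A value near 0 can hide a trend that turns with length. Medians of the shortest, middle and longest transcripts were 0.14, -0.01 and 0.10 from control to Ras. From Ras to EP3037 they were -0.12, 0.01 and -0.15. The length trend explained 4.6% of the variance in each of these comparisons and 0.8% from control to EP3037.

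Against the control, the combined effect of RasV12 with each construct was read. In the RNAi group 8 of 18 muscle and 5 of 12 fat body markers fell, and 4 of 28 neuronal and 4 of 30 photoreceptor genes rose. Of 10952 tested genes, 122 were higher and 66 lower. The photoreceptor fate list had 4 higher of 30: the row CG44037,svp (2.27-fold, overlapping 4 rows), salm (1.77-fold), salr (1.66-fold, q = 0.0192 in the authors' deposited table) and sev. The neuronal list had 4 higher of 28: the row Gr2a,futsch (2.65-fold) and the genes scrt (2.38-fold), cpo (2.21-fold) and brp (1.81-fold). Both had an adjusted p of 0.00562 by Fisher's exact test, with 7 and 9 adjusted over the list alone, and both lost it when the length trend was subtracted, with 0.704 and 0.698. At a q of 0.01 the photoreceptor list had an adjusted p of 0.152 and the neuronal list 0.000811. The trend also took the count of higher genes from 122 to 77. Muscle markers were lower in 8 of 18 cases (adjusted p = 3.28e-12 by Fisher's exact test, 10 adjusted over the list alone), such as the troponin and myosin genes TpnC73F (2.55-fold) and Mlc2 (2.23-fold), tropomyosin Tm2 (2.22-fold) and up (2.08-fold). Fat body markers were lower in 5 of 12 cases (adjusted p = 1.83e-07 by Fisher's exact test, 6 adjusted over the list alone), led by Lsp1gamma (9.05-fold).

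Haemocyte markers in the same comparison had 3 higher of 16, PPO2 (2.68-fold), PPO1 (2.20-fold, overlapping 5 rows) and Cg25C (1.72-fold, q = 0.0140 in the authors' deposited table). One was lower, NimC1 (4.15-fold, from 2.20 to 0.529 FPKM, q = 0.0325 in the authors' deposited table). The adjusted p for the higher calls was 0.00951, 0.0769 after the length trend was subtracted and 0.0712 at a q of 0.01, with 6 higher and 2 lower adjusted over the list alone. Ras MAPK components had 2 higher calls (Ras85D and sev), Ras targets 2 (mirr and sty), apoptosis 1 (Traf4) and heat shock 1 higher (Hsp70Bb) and 1 lower (Hsp70Bc), with no enrichment, and hnRNP genes 0 Cuffdiff calls with 6 higher at an unadjusted p at or under 0.05. CG10126 rose 6.43-fold, CG9119 3.53-fold (overlapping 8 rows, q = 0.0140 in the authors' deposited table), bnb 3.29-fold and CG18547 3.21-fold, and CR40469 fell 101-fold, Lsp2 6.07-fold and CR45108 5.84-fold. CG32726, at 2.22 FPKM in the control, was listed at 0 in the RNAi group.

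In the EP3037 group 28 of 11039 tested genes were higher than in the control and 43 lower. Glutathione transferases and cytochromes P450 were higher in 3 of 78 cases (adjusted p = 0.0343 by Fisher's exact test, 3 adjusted over the list alone): GstD1, an oxidative stress enzyme (1.80-fold, from 415 to 747 FPKM), Cyp4p2 (104-fold, from 0.470 to 48.9 FPKM) and Cyp4p1 (27.8-fold, q = 0.0359 in the authors' deposited table). At a q of 0.01 the adjusted p was 0.219. The same 3 genes were also higher from control to the RNAi group, GstD1 1.63-fold (q = 0.0399 in the authors' deposited table), Cyp4p2 86.1-fold and Cyp4p1 24.9-fold (q = 0.0359). There the adjusted p was 0.357 by Fisher's exact test, and 0.0439 after the length trend was subtracted, so these rises are not particular to EP3037. Cyp4p1 and Cyp4p2 are listed at one shared locus, so how reads were split between them is uncertain. Fat body markers were lower in 3 of 12 cases (adjusted p = 0.000827 by Fisher's exact test, 4 adjusted over the list alone), Lsp1gamma 3.10-fold, Fbp1 2.74-fold and Lsp2 2.58-fold. Muscle markers at 1 FPKM or more had a median log2 change of -0.49, with 8 of 17 lower by more than 0.5 and 0 higher. From control to the RNAi group the median was -0.87, with 11 of 17 lower, so the fall was not particular to that group. Other rises were in CG18547 (5.34-fold), CG30345 (2.87-fold), CG15630 (2.70-fold, overlapping 1 row) and roX2 (2.70-fold), and other falls in CR40469 (72.6-fold), CR45108 (5.30-fold), the cell adhesion gene Dscam4 (3.96-fold, overlapping 1 row) and Hsp70Bc (3.68-fold, uncertain as above, q = 0.0140 in the authors' deposited table). Heat shock genes had Hsp70Bb higher and stv also lower, with no enrichment. Photoreceptor fate, hnRNP, apoptosis and Ras target lists had 0 Cuffdiff calls here, with 1 higher and 1 lower, 0, 0 and 1 higher at an unadjusted p at or under 0.05.

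Calls were compared between the tables that share the Ras libraries. From Ras to the RNAi group and from Ras to EP3037, 17 genes were called in both, 4 higher and 13 lower in both, with 0 in opposite directions. The higher ones were Hml, the row CR45660,Pxn, regucalcin and CHKov1, and the lower ones included spok, nvd, phm, Lcp4, TwdlN, SP1029 and Sec61gamma, of which CHKov1 and Sec61gamma were chosen after their values were seen. Independent lists would share 0.0264 higher and 0.385 lower genes, and unchanged groups simulated against shared Ras libraries gave a mean of 0.229 and at most 3, when 14 of the 17 were among the genes simulated. From control to Ras and from Ras to EP3037, 26 genes were called in opposite directions, 21 higher then lower and 5 lower then higher, and 0 in the same direction. Among the first were tnc, bnb, Blimp-1, Np, CG14814 and the row CG12912,Hr46, and among the second CG12643, CR40976 and Hml. Independent lists would give 0.284 and 0.0415, and the simulation a mean of 0.205 and at most 2, with 24 of the 26 among the genes simulated. From control to Ras and from Ras to the RNAi group 15 genes were opposite, 9 higher then lower and 6 lower then higher, among them Sirup, ImpL3, CG45087 and roX2, against 0.265 and 0.0530 for independent lists and a simulated mean of 0.201, at most 3, with 12 of the 15 among the genes simulated. Part of each excess may come from the shared Ras libraries, which cannot be split in pooled values.

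**Figure D4:**
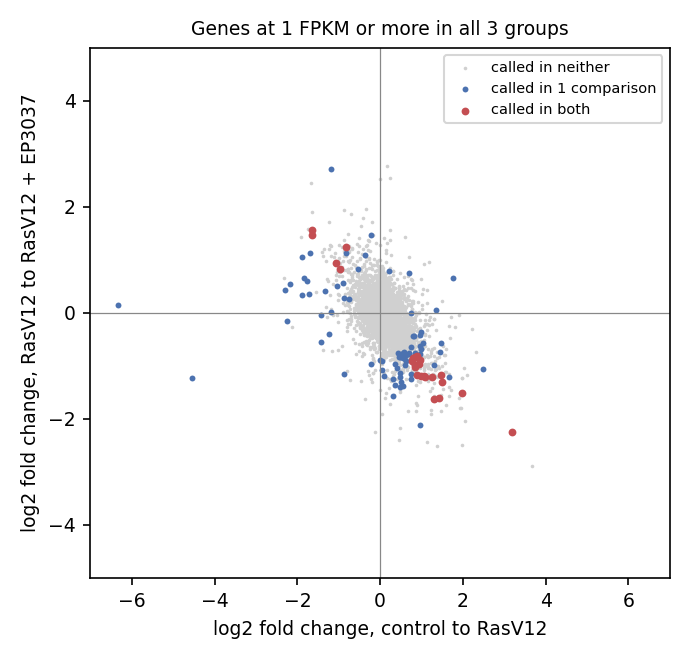
Each point is a gene at 1 FPKM or more in the control, Ras and EP3037 groups (8869 genes), with the log2 fold change from control to Ras on the horizontal axis and from Ras to EP3037 on the vertical axis. Red points, 24 genes called in both, lie in the quadrants of opposite sign; both axes share the Ras libraries, which alone gives a negative slope.

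The Spearman correlation across genes of these fold changes was -0.56 for control to Ras against Ras to EP3037, -0.21 for control to Ras against Ras to the RNAi group and 0.26 for the 2 comparisons from Ras. The covariances, -0.070, -0.042 and 0.058, were smaller in size than those of the simulated unchanged groups, -0.238, -0.234 and 0.239, so they give no estimate of a shared effect.

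The remaining lists had few calls in the 4 main comparisons, and the genes named here were chosen after their values were seen. JNK and wound response genes (25 or 26 tested) had Atf3 higher from Ras to the RNAi group and Thor lower in EP3037 against both Ras and the RNAi group. Glycolysis (15 tested) had ImpL3 in 3 comparisons and the aldolase gene Ald lower in EP3037 than in the RNAi group. The immune list (26 tested) had the complement-like gene Tep1 higher in EP3037 against both, by 1.86 and 1.40 on the log2 scale, and the receptor PGRP-LC lower against the RNAi group. Between the RNAi and EP3037 groups 1 lower call each fell in the cell cycle list (Caf1-180, of 47), the Hippo list (kibra, of 19), the cone and pigment cell list (ct, of 12), the splicing list (Doa, of 42), the Notch list (H, of 27), the ribosomal protein list (RpL13, of 91) and the brain neuron list (para, of 10), and 2 in the retinal determination list (Optix and toe, of 15). The Notch list had also 1 lower from control to Ras, the row kuz,mir-2489, as had the ribosomal protein list, the row RpL28,snoRNA:Or-CD11a,snoRNA:Or-CD11b. None of these lists was enriched. Hedgehog, Dpp, Wg and JAK-STAT genes (28 or 29 tested), ribosome biogenesis (28), antennal and peripodial markers (19) and salivary gland markers (8 to 10) had 0 Cuffdiff calls in the main comparisons, with 7, 6, 3 and 9 tests at an unadjusted p at or under 0.05 over the 4. Glial markers (15 or 16) had 1, Glt, which is also a haemocyte marker.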

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

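The tests of the share of haemocyte markers, of the share of ring gland genes and of ecdysone timing, and the alternatives that subtract the length trend or rescale the inputs, were chosen only after the results were seen. The genes listed in the next paragraph were picked out because Cuffdiff called a difference between the groups labelled hsrω RNAi and EP3037 in their direct comparison, the test of whether their changes against Ras differ. The changes of haemocyte and ring gland genes and the opposite calls weighed below come from comparisons with Ras or the control, and ring gland genes had 0 Cuffdiff calls in the direct comparison. The direct comparison called 191 genes, and 62 of these were also called against Ras, 10 in the RNAi group only, 51 in the EP3037 group only and 1 in both.

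Of the named genes among the 62, these were lower in the EP3037 group than in the RNAi group, as log2 values: bnb (-2.04), ImpL3 (-1.97), Sirup (-1.73), Thor (-1.69), Np (-1.60), tnc (-1.54), CG10126 (-1.53), CG14814 (-1.42), AGO3 (-1.25), CG45087 (-1.25), rno (-1.03), Psc (-0.89), PPO2 (-0.85), MESR4 (-0.84) and PPO1 (-0.76), with CG18294 listed at 0. Higher were yip7 (4.28), Jon65Aiv (3.6), Lcp4 (2.53), CG12643 (2.24), CG30345 (1.90), CR40976 (1.86), CR42861 (1.81), CR43148 (1.44) and Tep1 (1.40), with CG32198 and CG3397 listed at 0 in the RNAi group. ImpL3, Sirup, CG10126, CG45087, PPO2, PPO1 and CR42861 were called against Ras in the RNAi group only, Lcp4 in both, and the rest in the EP3037 group only. The log2 changes of Lcp4 against Ras were -4.78 and -2.25. In the direct comparison q was 0.0140 for PPO2 and 0.0325 for PPO1 in the authors' deposited table.

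The 167 genes that were lower in the EP3037 group than in the RNAi group lay on long transcripts, with a median of 5804 nt against 1816 nt for tested genes. With the trend of fold change on length subtracted, 46.6% of the 191 calls remained, between the bounds set in advance of under 20% and over 50%, so a length-dependent difference between libraries as the whole cause cannot be told apart from other causes. With the test rescaled to 3 inputs for the RNAi group 73.3% remained, between bounds of under 50% and over 80%, so the sample entered as 2 inputs also stays open. The Spearman correlation with length across genes was 0.37 from control to the RNAi group, 0.44 from Ras to the RNAi group and -0.12 from control to EP3037. An effect of the constructs, or of dco2, which the labels list in the control and Ras groups only, stays open as untested.

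From Ras to the RNAi group 8 of 16 haemocyte markers (higher), 3 of 11 ring gland genes (lower, list median -0.97) and 1 of 11 fat body markers (lower, -0.83) were called, and 0 of 9 salivary gland markers, whose 4 members at 1 FPKM or more had a median of -0.31, and -0.07 after the length trend was subtracted. The median of the haemocyte markers was 1.12 on the log2 scale, and 1.03 after the length trend was subtracted. Across all genes, the median went only from -0.24 in the shortest transcripts to 0.10 in the longest. Subtraction could therefore hardly bring the haemocyte median under the bound of 0.6 set in advance, so staying above it was no independent test. The values show only that the fitted length trend was small beside this change. Of 14 haemocyte markers at 1 FPKM or more, 8 (57.1%) were higher by more than 0.5, among the most abundant PPO1 from 37.8 to 81.3 FPKM, while lz, Lamp1, crq, Ppn and He were not, so more haemocytes in the RNAi samples cannot be told apart from a change within some of these cells. The gene lz is also in the photoreceptor fate list, so its level can come from disc cells and weighs little in this share. Of ring gland genes 80% were lower by more than 0.5, spok from 53.9 to 15.0 FPKM and sad from 42.8 to 20.2, and 80% were so from Ras to EP3037 as well, which is what less ring gland tissue on the dissected discs of both groups might give, as a hypothesis. No sort or gate removed either tissue, and an effect of the RNAi construct or of dco2 on these genes stays open as untested. Whether the dissected samples also differed in fat body, muscle or midgut tissue was not tested. Changes of those markers therefore cannot be assigned to RasV12 or to the constructs alone.

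Of the genes moved from control to Ras, 26 were called in the opposite direction from Ras to EP3037. In 0% of 1000 simulations of unchanged groups did the shared Ras libraries give as many, which argues against their chance spread alone only within that model. The model used normally distributed noise and no true change in any group. Its covariance was -0.238 against -0.070 observed, so its noise was not matched to these data, and chance spread outside the model stays open. The median change of the ecdysone response list lay at percentile 99.99 of matched random lists from control to Ras and at 0.04 from Ras to EP3037. This is what a difference in developmental time between the samples may give, but it was not particular to this list. The snoRNA, snRNA and cuticle protein lists lay at percentile 100 and then 0, and the microRNA list at 99.88 and then 0. Blimp-1 and the row CG12912,Hr46 belong to both the ecdysone list and the 26 genes, and the shared Ras libraries tie the 2 percentiles. The ecdysone median from Ras to EP3037 went from -0.28 to -0.14 once the length trend was subtracted. Across all genes, medians of the shortest and longest transcripts were 0.14 and 0.10 from control to Ras. They were -0.12 and -0.15 from Ras to EP3037. Whether transcript length contributed to the opposite calls was not tested and stays open. A single Ras sample that stands apart cannot be looked for in pooled values and stays open. An effect of EP3037 or of dco2 stays open as untested.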

How the results depend on the processing

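The alternatives with the unadjusted p, without markers of other tissues, with the length trend subtracted and with the test rescaled to 3 inputs were chosen only after the data were seen. No paired analysis was possible because each group has 1 pooled value per gene; leaving out single samples, a replicate block and other splits of the samples were not run for the same reason. Depth is unknown, so what it limits was not measured. The 12 counts of higher or lower genes stayed within 1.5 times with adjustment within each comparison, a minimum of 1 FPKM, a minimum span of 200 nt and centring, and the 6 counts with the RNAi group did so with the rescaled test. The rescaled test can only remove calls by construction. It kept 59 of 81 from Ras to the RNAi group, 140 of 191 from the RNAi group to EP3037 and 137 of 188 from control to the RNAi group. All 238 log2 values of named genes kept their sign with pseudocounts of 0.1 and 1 and with centring. A pseudocount added to both groups cannot change a sign by construction. Centring could not change the counts either: the medians lay between -0.056 and 0.045, and the smallest called log2 change was 0.66. Of the 17 list enrichments 15 kept a median in the outer tail of matched random lists, and all 17 held against the background of at least 1 FPKM, which added 2 from control to Ras, heat shock and glutathione transferases and cytochromes P450.

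At a q of 0.01 the counts became 27 higher from control to Ras, 40 lower from Ras to the RNAi group, 9 higher and 37 lower from Ras to EP3037, 15 higher and 87 lower from the RNAi group to EP3037, 74 higher from control to the RNAi group, and 17 higher and 24 lower from control to EP3037; enriched lists fell from 17 to 9, calls shared by the comparisons from Ras from 17 to 9, and opposite calls between control to Ras and Ras to EP3037 from 26 to 11. A minimum of 2-fold gave 26 higher from control to Ras, 29 lower from Ras to the RNAi group, 39 lower from Ras to EP3037, 58 lower from the RNAi group to EP3037 and 52 higher from control to the RNAi group. Both settings can only remove gene calls by construction. The unadjusted p, which adds calls by construction, gave 371 higher and 138 lower from control to Ras, 147 and 420 from Ras to the RNAi group, 191 and 460 from Ras to EP3037, 337 and 699 from the RNAi group to EP3037, 627 and 330 from control to the RNAi group, and 201 and 188 from control to EP3037. Without markers of other tissues 11 in place of 19 were higher from Ras to the RNAi group. With the length trend subtracted 33 higher and 44 lower in place of 46 and 39 were called from control to Ras, and 27 were lower from Ras to the RNAi group, 39 lower from Ras to EP3037, 72 lower from the RNAi group to EP3037 and 77 higher from control to the RNAi group, and 10 list enrichments were called, 9 of the 17 and 1 new, of glutathione transferases and cytochromes P450 from control to the RNAi group; the cause was not tested.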

Other observations

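The test of ring gland and midgut genes below was chosen only after the results were seen, as were the genes named outside the rule. Ring gland genes, most of them enzymes of ecdysone synthesis, had 3 lower of 11 tested in each comparison from Ras: spok, nvd and phm in both. The list's median log2 change was -0.97 from Ras to the RNAi group and -1.03 from Ras to EP3037, with 6 and 5 lower adjusted over the list alone, and 0.30 from control to Ras, with 0 Cuffdiff calls and 1 higher at an unadjusted p at or under 0.05. Between the RNAi and EP3037 groups there were 0 Cuffdiff calls, and 1 higher and 1 lower at that level. Against the control, spok and nvd were lower in the RNAi group and phm and spok in the EP3037 group. Of the 11 genes 10 were at 1 FPKM or more in every group and 1 is in another list; of the 18 haemocyte marker rows 14 were at that level in every group and 2 are in another list.

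Digestive enzymes of the midgut stood out in the EP3037 group. From Ras to EP3037 4 of 20 tested were higher, yip7 and Jon65Aiv and the trypsin genes alphaTry and epsilonTry, which were listed at 0 in the Ras group and at 1.53 and 0.647 FPKM in the EP3037 group. From the RNAi group to EP3037 4 of 20 were higher, Jon65Aiii, yip7, Jon65Aiv and Jon25Bi, with 4 also adjusted over the list alone, and from control to EP3037 1 was higher, alphaTry. In the comparisons of control, Ras and the RNAi group the list had 0 Cuffdiff calls; at an unadjusted p at or under 0.05 it had 0 from control to Ras, 4 from Ras to the RNAi group and 3 from control to the RNAi group, all higher. Jon65Aiii was at 0.499 FPKM in the control, 0.224 in Ras, 1.46 in the RNAi group and 35.6 in EP3037.

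The lists of short noncoding RNAs had higher medians in the Ras group, with few calls and no enrichment by Fisher's exact test from control to Ras: 2 higher and 1 lower for snoRNA, 1 and 1 for snRNA, and 0 and 2 for microRNA. The median log2 change was 0.45 for snoRNA, 0.76 for snRNA and 0.16 for microRNA from control to Ras, over the 233 of 260, 22 of 23 and 74 of 108 tested rows not listed at 0 in either group. It was -0.33, -0.52 and -0.33 from Ras to the RNAi group (243, 23 and 79 rows), -0.35, -0.43 and -0.22 from Ras to EP3037 (238, 22 and 76) and -0.03, 0.11 and 0.01 from the RNAi group to EP3037 (253, 22 and 81). From control to Ras the calls were snoRNA:U3:9B, snoRNA:Psi28S-3342 and snRNA:U5:34A higher, and snRNA:U2:34ABa and the rows RpL28,snoRNA:Or-CD11a,snoRNA:Or-CD11b, kuz,mir-2489 and mir-4940,nwk lower. These rows also hold the genes RpL28, kuz and nwk, so their falls cannot be assigned to the small RNAs. From Ras to the RNAi group 4 snoRNA rows and from Ras to EP3037 2 were lower, and between the last groups 0 were called, with 2 higher and 3 lower at an unadjusted p at or under 0.05 in Cuffdiff. FPKM summed over rows with a span under 200 nt came to 18104 in the control, 87492 in Ras, 22817 in the RNAi group and 27346 in EP3037. One snoRNA row was listed at 60358 FPKM in Ras and at 0 in the control, and without it the sums in the same order were 18104, 27134, 19704 and 20209. The tRNA list matched 0 rows. Of 12 or 13 tested histone rows His2B:CG33868 was lower in both comparisons from Ras, with 0 calls in the other main comparisons.

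In the list of sex-related genes (9 tested) roX2 alone was called, higher from control to each Ras group and lower from Ras to the RNAi group; roX1, the partner noncoding RNA, was at 137, 314, 322 and 297 FPKM in control, Ras, RNAi and EP3037 without being called from control to Ras (p = 0.0441 in the authors' deposited table). Glutathione transferases and cytochromes P450 had 3 higher of 74 from control to Ras, Cyp4p2, Cyp4p1 and GstD3 (adjusted p = 0.0505 by Fisher's exact test, and 0.0426 against a background of genes at 1 FPKM or more), GstD3 lower from Ras to the RNAi group, and 0 in the other main comparisons. Muscle markers had 1 call in the main comparisons, TpnC73F, lower from Ras to the RNAi group, of 18 tested.

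Across the 3 groups with RasV12, 25 gene rows were called against the control in the same direction, 7 higher and 18 lower. On chromosome 3L, 6 neighbouring rows between 22643881 and 22649287, CR45381 and CG33766 to CG33770, were at 0.841 to 1.77 FPKM in the control and listed at 0 in each Ras group. Elsewhere on 3L, mthl8 was at 0.765 FPKM in the control and also listed at 0 in each. The small nuclear RNA snRNA:U2:34ABa was at 370 FPKM in the control and at 15.8, 7.35 and 6.74 in Ras, RNAi and EP3037, and Cyp4p2 went from 0.470 to 44.8, 40.4 and 48.9. Whether the parental chromosomes differ at these loci was not analysed here.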
